A study of Mus musculus with 2 samples.

How the data were processed

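Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole mouse uterus with an antibody against SF1 (NR5A1), an orphan nuclear receptor that drives steroid hormone synthesis in the adrenal gland and gonads. The mice had their ovaries removed at 6 weeks of age and were left for 2 weeks, so that the tissue was taken at 8 weeks. Per the labels' protocols, libraries were made from the ChIP DNA and from input DNA, which is sonicated chromatin taken without antibody, and were sequenced as single-end reads of 50 nt. The series holds 2 libraries, 1 SF1 ChIP and 1 input. The labels give no replicate of either, so no comparison here has a replicate check and no spread between animals can be given.

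Per the submitters' processing notes, reads were aligned with BWA to the mouse build mm9. The aligner's version, the region caller, its threshold, and the use made of the input library are not given in the sources used here. The deposited file is 1 list of regions from the ChIP library, with no header line and 5 columns that hold chromosome, start, end, a running name and a whole number. That number was taken here as the score the authors gave each region. The deposited scores carry no name, so it is open whether they count reads at the summit, a normalized height or another measure. They were compared only within this list, by rank, by minimum score, by median and mean, and by correlation with width and between adjacent regions. One test in the closing section, with its scan of multiples, treats them as proportional to signal, which is an assumption. Coordinates are printed as deposited. Whether starts count from 0 or from 1 is not stated, which leaves them uncertain by 1 bp. No read totals were at hand, so the sequencing depth of both libraries is unknown. A separate file for the input library was not used here.

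The running names had 0 missing numbers. Regions did not overlap. No mm9 chromosome lengths, gene annotation or sequence were at hand. The gene table supplied is on GRCm38.p6, and its coordinates were not set against those of the regions. For that reason the distances to transcription start sites, the tests of gene lists, the search for the SF1 binding motif and the genes assigned to the highest regions, all of which had been fixed before the data were examined, were not run. The rule for named items was kept for regions in place of genes, so the text names the 20 regions with the highest score. Chromosome span was taken from the start of the first region to the end of the last one, in place of chromosome length, and the chi-square test planned on chromosome lengths was not run.

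Densities were computed as regions per Mb of span. Their 95% intervals come from 10000 bootstrap samples of 5 Mb blocks, since neighbouring regions are not independent, and those for medians and for the means in sparse windows from 2000 samples. Shares of regions carry exact Clopper-Pearson 95% intervals, which treat regions as independent. The bootstrap intervals describe how evenly regions are spread in this 1 library, while the exact ones rest on counts alone. Having a near neighbour is shared between regions, so independence does not hold for those shares. Regions lie in groups along a chromosome, so it does not hold for the share of regions on X either. Neither kind of interval describes the spread between animals. The distance from each region to its nearest neighbour was taken between their edges. The share with a neighbour within 10 kb was set against 1000 placements of the same regions at random positions within the span of their own chromosome, and against 1000 placements in which each region moved by up to 500 kb to either side. Regions that overlapped after placement were merged. Runs of regions less than 10 kb apart were set against 200 random placements. No p-value across regions is given, because regions of 1 library are not replicates.

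The choices of 10 kb, 500 kb, 5 Mb blocks and 1 Mb windows were made after the list had been seen. The alternatives tried were the top 50% and the top 10% of the regions by score, merging of regions less than 1 kb apart, neighbour distances of 5 and 25 kb, covered length in place of the number of regions, and other definitions of chromosome length. The code was tested on simulated regions with known answers, and all 5 simulations met the bound set for them, which was the range of random placements, a 95% bootstrap interval or a fixed range of a correlation. An X-to-autosome ratio of 0.2 planted in simulated regions came back as 0.178, with 0.2 inside its 95% interval. Those simulated regions lay at uniform random positions, so the intervals were not checked for regions that lie in groups. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.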

Results

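SF1 (NR5A1) is an orphan nuclear receptor best known as a regulator of steroidogenic genes in the adrenal cortex and the gonads. The series concerns SF1 in the endometrium and the formation of cystic glands, and the ChIP-seq experiment addressed where SF1 is found on chromatin in the uterus. Whole uterus came from C57BL6/6J mice at 8 weeks of age, 2 weeks after removal of the ovaries, when the hormones made there had been depleted. The design comprised 1 SF1 ChIP library and 1 input library. The data are the authors' list of regions from the SF1 ChIP on mm9, with 1 score per region. Whether SF1 itself binds at these regions was not tested here. Read totals were not at hand, so the depth is unknown. The labels do not say whether the mice carried an SF1 transgene or whether the tissue came from 1 animal or a pool. No replicate is named, and every value below describes this 1 library.

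SF1 ChIP regions were found on all 19 autosomes and on X, 16249 in total. They covered 42.4 Mb. The list held 0 regions on Y, a chromosome that the uterus of female mice does not carry, and 0 on the mitochondrial genome. Whether either sequence was searched is not stated. The median region was 2089 bp wide, with quartiles of 1633 and 2961 bp, and widths ran from 686 to 31333 bp. The median score was 17, with quartiles of 13 and 22, and scores ran from 8 to 156. The most frequent score was 14, given to 1371 regions, while only 12 regions had the lowest score of 8. Scores under 13 were given to 2849 regions, 17.5% of the list.

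High scores were rare. A score of 50 or more was given to 317 regions, and a score of 100 or more to 10 regions. The highest score, 156, belonged to a region of 3430 bp on chromosome 10 (127518959 to 127522389). It was followed by a region of 6680 bp on chromosome 17 (39979688 to 39986368) with a score of 141. A broad region of 23255 bp on chromosome 8 (73205360 to 73228615) had a score of 136. On chromosome 15, a region of 2540 bp (81701470 to 81704010) scored 129. On chromosome 7, a region of 5103 bp (134486032 to 134491135) scored 125. On chromosome 18, a region of 3554 bp (35112770 to 35116324) scored 117. The other four regions at 100 or above lay on chromosome 2 (73747929 to 73750550, score 106), chromosome 12 (10396801 to 10399037, score 104), chromosome 17 (26338229 to 26345976, score 101) and chromosome 1 (65084442 to 65093347, score 100).

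The regions ranked 11 to 20 scored between 96 and 87. Chromosome 7 held 3 of them, at 146548524 to 146552277 (score 93), 133939819 to 133945575 (score 92) and 91112646 to 91115860 (score 92). Chromosome 11 held 2, at 4110182 to 4120789 (score 91) and 102267266 to 102272102 (score 87). The remaining ones lay on chromosome 2 (135383805 to 135387227, score 96), chromosome 14 (26403247 to 26412471, score 92), chromosome 9 (86609184 to 86613189, score 92), chromosome 19 (47992744 to 47995368, score 90) and chromosome 17 (8474101 to 8477502, score 87). The 20 highest regions were spread over 13 chromosomes, and 0 of them lay on X. Which genes these regions lie in or beside was not analysed here, nor whether any of them, the second-ranked region on chromosome 17 included, lies in repeated sequence, where reads from many copies can pile up and give a high score without SF1.

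Broad regions made up a small part of the list. Of all regions, 134 were wider than 10 kb, which is 0.825% (95% interval 0.691 to 0.976%), and they held 4.18% of the covered sequence. The widest lay on chromosome 10 (79600977 to 79632310) and spanned 31333 bp with a score of 62. It was followed by regions on chromosome 7 (108053182 to 108081986, 28804 bp, score 47) and chromosome 11 (78906101 to 78932311, 26210 bp, score 35). On chromosome 2, a pair of broad regions, 30501789 to 30520016 (score 72) and 30560479 to 30581744 (score 66), lay in 1 window of 1 Mb. Wider regions scored higher. The median score was 13 in the narrowest 10% of the regions, those up to 1387 bp, and 24 in the widest 10%, those of 4356 bp or more. Across regions, which are not independent replicates, the Spearman correlation of score and width was 0.463 and the Pearson correlation of their log2 values was 0.477. A score of 50 or more was given to 28 of the 134 regions over 10 kb, against 317 of all 16249 regions. The order by score and the order by width still differed, since most regions over 10 kb scored under 50.

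The autosomes carried 6.71 regions per Mb of span (95% block bootstrap interval 6.22 to 7.20). Chromosome 11, a gene-rich mouse chromosome, stood highest with 1352 regions, or 11.4 per Mb (8.22 to 14.6). Its density was 1.76 times that of the other autosomes together (1.27 to 2.30). Chromosome 19 followed at 8.62 per Mb (5.23 to 12.8), chromosome 7 at 7.98 (6.25 to 9.83) and chromosome 9 at 7.95 (6.14 to 9.87). The lowest autosomes were chromosome 3 at 4.67 per Mb (3.25 to 6.33), chromosome 16 at 5.21 (3.57 to 6.92) and chromosome 1 at 5.28 (3.97 to 6.68). The interval of chromosome 11 lay wholly above those of chromosomes 3, 16 and 1, while the intervals of autosomes next to each other in this order overlapped. Median scores were 16 or 17 on every autosome.

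**Figure D1:**
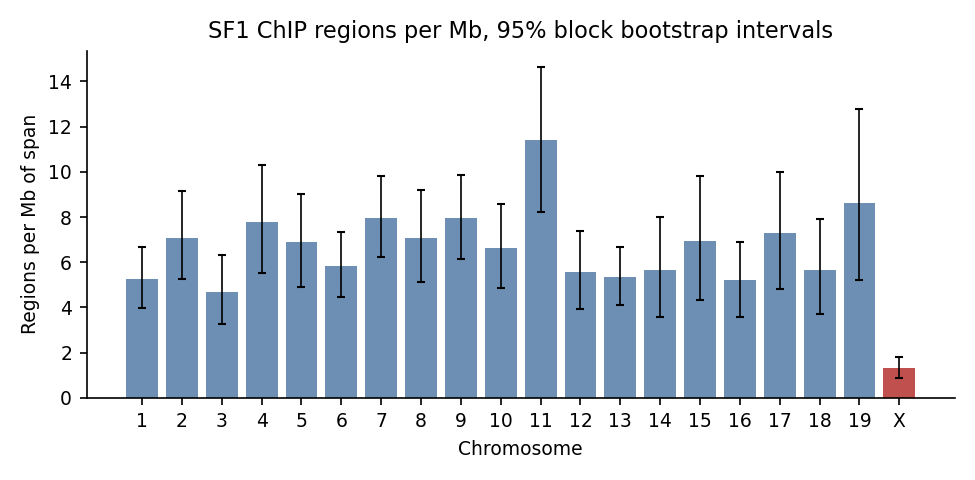
Number of SF1 ChIP regions per Mb of chromosome span (y axis) on each chromosome (x axis), with bars from 0 and error bars for the 95% interval of a bootstrap over 5 Mb blocks; autosomes are blue and X is red. Chromosome 11 reaches 11.4 regions per Mb and X 1.32, below the interval of every autosome.

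The X chromosome stood apart from the autosomes. It held 208 regions, 1.28% of the list (1.11 to 1.46%), and 1.32 regions per Mb (0.873 to 1.80). The X density was 0.196 times the autosomal one (0.130 to 0.270), whereas the lowest single autosome, chromosome 3, reached 0.681 times that of the other autosomes. Regions on X were also narrower and scored lower. Their median width was 1592 bp against 2096 bp on autosomes, a difference of -504 bp (-601 to -429). Their median score was 15 against 17, a difference of -2 (-3 to -1). The highest score on X was 58, and 147 autosomal regions scored above it. A score of 50 or more was given to 2 X regions, 0.962% (0.117 to 3.43%), and to 315 autosomal regions, 1.96% (1.75 to 2.19%), so those shares were not told apart at these numbers.

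The shortfall on X was deeper among regions with higher scores. The X-to-autosome density ratio was 0.170 (0.112 to 0.233) for scores of 13 or more, 0.121 (0.0689 to 0.183) for 20 or more and 0.0840 (0.0272 to 0.151) for 30 or more, where X had 10 regions left. These sets are nested and their intervals overlap. Counting only scores of 25 or more multiplied the ratio by 0.582 on X, and by between 0.785 and 1.21 on the 19 autosomes. With stretches over 1 Mb that held no region taken out of every chromosome's span, which shortens a sparse chromosome most by construction, the ratio was 0.554 (0.412 to 0.686).

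**Figure D2:**
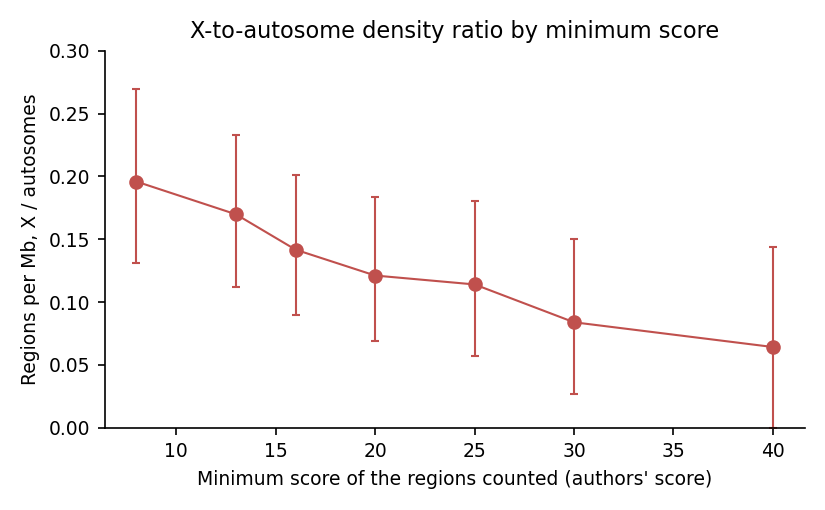
Ratio of the number of SF1 ChIP regions per Mb on X to that on the autosomes (y axis) among regions at or above a minimum score (x axis, the authors' score); points are the ratio and error bars the 95% interval of a bootstrap over 5 Mb blocks. The ratio is 0.196 over all regions and 0.0840 at scores of 30 or more.

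SF1 ChIP regions lay in groups along the chromosomes. Of all regions, 6987 had another region within 10 kb, which is 43.0% (42.2 to 43.8%). When the same regions were placed at random on their chromosomes, the share was 12.9% in the median placement and 14.1% in the highest of 1000. When each region was only moved by up to 500 kb, which keeps the coarse density along the chromosome, the median was 24.2% and the highest 25.5%, so the excess was 18.8 percentage points in place of 30.1. It was 13.5 points when regions less than 1 kb apart were also merged. On X alone, 23.6% of regions had a neighbour within 10 kb, against 8.65% in the highest of 1000 random placements over the span of X. Those placements did not keep the coarse density along X, and moves by up to 500 kb were not run for X alone. Regions with a near neighbour were wider than the others, with medians of 2403 and 1927 bp and a difference of 476 bp (424 to 534). Their median score was 17 in both classes, and the interval of the difference ran from 0 to 1. Of the regions over 10 kb wide, 82.1% (74.5 to 88.2%) had a near neighbour, against 42.7% (41.9 to 43.4%) of the others.

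**Figure D3:**
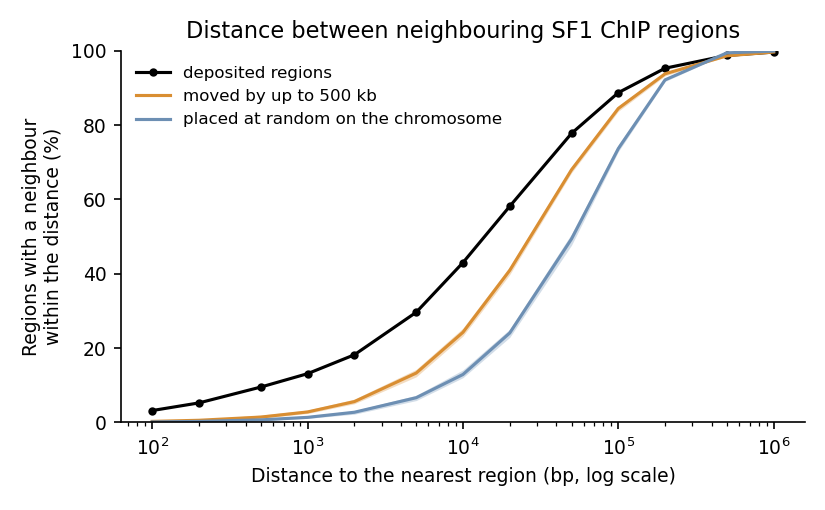
Share of SF1 ChIP regions in percent (y axis) that have another region within a given distance in bp (x axis, log scale), for the deposited regions (black), for regions moved by up to 500 kb (orange) and for regions placed at random on their chromosome (blue); lines are medians and bands the range of 100 placements. At 10 kb the deposited regions reach 43.0%, above both kinds of placement.

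Groups of regions less than 10 kb apart numbered 2702. Of these, 164 groups held 5 or more regions each, 972 regions together, while the highest of 200 random placements gave 3 such groups. The largest group held 16 regions over 120206 bp on chromosome 12 (80981176 to 81101382), with a highest score of 45. The next held 13 regions on chromosome 14 (26275513 to 26388282), 12 on chromosome 11 (59693594 to 59779471), and 11 each on chromosome 1 (74037328 to 74117930) and chromosome 8 (34979325 to 35042945). The largest group in any random placement had 7 regions. These placements were over the whole chromosome and did not keep its coarse density. Groups were not set against regions moved by up to 500 kb, or counted after merging, so how much of the contrast would remain there is not known. The group on chromosome 14 and the region at 26403247 on that chromosome, which scored 92, lay in the 1 Mb window with the most regions, from 26 to 27 Mb, which held 45 regions covering 22.3% of its sequence.

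Other dense windows were at 129 to 130 Mb of chromosome 4 with 44 regions, and at 80 to 81 Mb of chromosome 10, 167 to 168 Mb of chromosome 2 and 75 to 76 Mb of chromosome 18 with 43 each. Windows with 20 or more regions numbered 198 and held 5222 regions. Chromosome 11 had 28 of these windows and X had 0, its fullest window holding 18. At the other end, 592 of 2406 autosomal windows (24.6%) and 96 of 160 windows on X (60.0%) held no region. The 3 longest stretches without a region were all on X, at 103382518 to 130593205 (27.2 Mb), 20528401 to 34090468 (13.6 Mb) and 54646530 to 66928381 (12.3 Mb). The longest on autosomes were on chromosome 15 (13102752 to 25293971, 12.2 Mb) and chromosome 14 (106341388 to 118437877, 12.1 Mb). An empty window means only that no region passed the authors' threshold there, and the share of each window to which reads could be aligned is not known here.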

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

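Stricter thresholds and merging were planned before the data were examined for the number of regions, and the top 50% by score for the regions per chromosome; the other alternatives here were chosen after seeing the data. By construction, the top 50% by score (17 or more, ties included) held 8349 regions and the top 10% (31 or more) 1626, and merging regions less than 1 kb apart left 15113. The X-to-autosome density ratio of 0.196 stayed below 1 under all 5 alternatives run. It was 0.0653 (0.0188 to 0.119) in the top 10% by score and 0.554 when stretches over 1 Mb without a region were taken out of every span, which shortens X most by construction. It stayed within the interval of the main value in the top 50% by score (0.139), with length counted from position 0 (0.193) and with covered length in place of the number of regions (0.138). The ratio of chromosome 11 to the other autosomes ranged from 1.35 to 1.95 over 4 alternatives. The excess of regions with a near neighbour lay between 13.5 and 34.1 percentage points over 7 alternatives, above the highest placement in each; the lowest value came with regions merged within 1 kb and moved by up to 500 kb. No paired analysis was possible because the series holds 1 ChIP and 1 input library, and for the same reason no replicate could be left out. The settings listed beforehand for start sites, gene lists and the SF1 motif were not run, since no mm9 annotation or sequence was used here. What depth does to the list is unknown, since no read totals were at hand. Of the regions, 17.5% scored under 13, below the mode of 14. The X-to-autosome ratio moved between 0.0643 (minimum score of 40) and 0.196 (no minimum). The former rests on 3 X regions, with an interval of 0 to 0.144.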

Other observations

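The tests of X regions reported here, apart from that of sparse surroundings, and the test of adjacent scores were chosen after the list had been seen; the tests of neighbour distance and sparse surroundings were written down before their results.

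The X chromosome had fewer regions, and lower scores, than the autosomes. Empty stretches over 1 Mb do not account for all of it, since the ratio was 0.554 (0.412 to 0.686) after they were taken out, a step that raises the ratio of a sparse chromosome by construction and still left it under the bound of 0.8 set for this explanation. Sparse surroundings do not account for the lower scores either: in 1 Mb windows with 3 or fewer regions, 69 X regions had a mean score of 15.8 and 1062 autosomal regions a mean of 18.7, a difference of -2.98 (-4.29 to -1.22). A signal on X at 0.5 times the autosomal level under 1 common threshold could be neither excluded nor singled out. The test assumed scores proportional to signal, and as many sites per Mb on X as on the autosomes. Equal site density is not given, since single autosomes ran from 0.681 to 1.76 times the density of the other autosomes. Under both assumptions, X regions at a given minimum score would be as dense as autosomal regions at 2 times that score. The ratio of those densities was 0.824 (0.536 to 1.15) for a minimum of 13 on X. It was 0.918, 0.964 and 1.10 for 16, 20 and 25, but 0.335 (0.220 to 0.465) over the whole list, from 8 up. Those minimum scores are nested, with 149, 88, 45 and 23 X regions, so they are not independent, and scores under 13 are thinly filled in the list, which leaves open whether the value from 8 up counts against it. Multiples from 1 to 3, 9 in all with 2 among them, were tried under the same assumptions at those 4 minimum scores. All 4 intervals held 1 only at multiples of 2 and 2.25. At 1.75 only the interval for a minimum of 25 held it, and 6 multiples had 0 intervals that held it. The list from 8 up was not part of that scan. Fewer sites per Mb on X would put the expected ratio below 1, so the scan does not single out these multiples. The inactive X of female tissue, a lower number of binding sites, poorer alignment on X and the way the input was used were not tested and stay open.

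The grouping of regions within 10 kb was weighed against 2 explanations. Some gaps were short enough for 1 enriched site to have been split into several listed regions: 262 gaps between neighbours were under 100 bp, the smallest being 1 bp, and 1136 of 16229 gaps (7.00%) were under 1 kb. After merging across gaps under 1 kb, 35.6% of regions still had a neighbour within 10 kb, against 13.2% in the highest random placement, so splitting at that scale is not the whole of the pattern. Differences in density at the scale of 1 Mb are not the whole of it either. Moving regions by up to 500 kb gave at most 25.5% against 43.0% observed, and at most 23.5% for the merged regions. Such moves also level differences in density at finer scales, so finer changes between gene-rich and gene-poor sequence were not tested. Splitting across gaps above 1 kb, density differences at finer scales, and several SF1 sites within 1 gene or regulatory domain all stay open.

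A further hypothesis, that neighbouring regions share a level of signal, was not borne out. Adjacent regions 1 to 10 kb apart had a Spearman correlation of scores of 0.00592 over 3149 pairs, against 0.0510 in the highest of 1000 shuffles within chromosomes. The correlation was -0.0165 over 1136 pairs under 1 kb apart and 0.00436 over 7730 pairs between 10 and 100 kb apart, in each case below the highest shuffle. Shuffles among regions of like width, which carry the likeness in width of neighbours, gave higher medians of 0.0699 under 1 kb, 0.0408 at 1 to 10 kb and 0.0242 at 10 to 100 kb, and 1, 25 and 41 of 1000 of them were as low as the observed values, so adjacent scores up to 100 kb apart were less alike than in most of these shuffles. Over 3747 pairs between 100 kb and 1 Mb apart the correlation was 0.0268, and 849 of 1000 such shuffles were as low or lower.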
